A study of Mus musculus with 11 samples.

How the data were processed

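Nucleus accumbens enriched in shell was punched bilaterally (0.5 mm) from 3 cryosections of 300 µm per brain in behaviourally untested male mice, and 100 ng of total RNA per mouse was converted to biotinylated cDNA, per the labels' protocols. Each array held the RNA of a separate mouse. The arrays were assigned to 6 WT and 5 Rarb-null mice from the sample titles and the series design text; the extraction protocol gives the group sizes the other way round, and the Rarb level was checked against the titles for that reason. Mutants and WT littermates came from heterozygous crosses on a mixed C57BL/6J and 129 background, per the labels.

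The deposited values were log-scale expression after RMA, per the labels and the submitters' processing notes. RMA subtracts background, normalises quantiles across arrays and summarises the probes of a probe set, which reduces differences in overall brightness and compresses folds of dim probe sets. That the deposited values are on a log2 scale was inferred from their range. The software version, the annotation used and whether all arrays were normalised together were not given in the sources used here. No batch, scan date or background signal was used, so signal over background could not be measured, and the level of a gene relative to other genes served as the filter on dim genes.

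Gene names came from a platform annotation table, with symbols updated through Entrez identifiers for 21698 probe sets against a RefSeq gene table of assembly GRCm38.p6, which also gave the order of genes along the chromosome of Rarb. The build behind the array annotation is not given in the sources used here, so no coordinates are printed. Of 35556 probe sets, 21789 had 1 symbol, 1621 had several and 12146 were not in the table; only those with 1 symbol entered the comparison. A gene with several probe sets was represented by the one with the highest mean over all arrays. This concerned 846 tested genes; among 176 such called genes, 135 had a further probe set above the filter, and in 14 it went in the opposite direction. Genes with a mean above the 40th percentile (log2 6.99) were tested, 11963 of 19938.

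Genotypes were compared with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes, no covariates) on the deposited log2 values, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Lists of genes were tested with limma's camera (preset correlation 0.01, and again with an estimated one), fry, and a two-sided exact permutation test of the mean level per array over all 462 splits; 24 of 26 lists had at least 4 measured members. Each list was also compared with 10000 random lists matched on mean level. Called genes near Rarb were counted with Fisher's exact test within 100 protein-coding genes on each side. The cortical marker level was tested as a covariate, with 10000 Freedman-Lane permutations for list means. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

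The groups, lists, tests, thresholds and most alternatives were fixed before the data were examined. Genes were named by a rule: Rarb, the 12 largest rises and 12 largest falls among called genes, and up to 4 members of each list with the smallest p, repeats counting under both. Crabp1, Rara, Rarg, Id4, Cnr1, Drd1, Penk, Wfs1, Nrgn, Slc4a11, Homer1, Rgs4, Htt, Slc17a7, Mbp, Thrb, Gng2 and Synpr were named after their values were seen. So were the TRPC, BRINP and neurofilament genes among the other observations. The lists come from textbook knowledge and hold markers of projection neurons, other neurons and glia, retinoid genes, genes lower in Huntington disease, and signalling genes.

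The procedure was tested on simulated data with the means and spread of these arrays, for Rarb-null against WT over 11963 genes. It recovered 74.6% of genes changed by log2 0.25 and 100% of those changed by 0.5 and by 1, with 11 false calls among 11749 unchanged genes. The list given a shift was called and 0 of the other lists were. Genes were simulated independently, whereas the correlation estimated for the projection neuron list was 0.31. The simulation therefore does not measure how often lists of correlated genes are called falsely.

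Alternatives were no filter, a stricter filter at the 60th percentile, and centring of each array on the median of its tested genes. Further ones were repeated quantile normalisation, a trended and robust variance, array weights, the mean of probe sets and a block for the replicate number. Others were oligodendrocyte or cortical marker covariates, other thresholds, other windows around Rarb, and leaving out each array in turn. Cyclic loess normalisation and a set without WT replicates 3 and 4 and Rarb-null replicate 5, whose cortical marker levels were extreme, were chosen after seeing the data.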

Results

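The data set held 11 arrays, each hybridised with RNA from the nucleus accumbens of 1 male mouse aged 4 to 5 months: 6 wild-type (WT) mice and 5 littermates lacking Rarb, the gene of retinoic acid receptor beta. The nucleus accumbens is the ventral part of the striatum, whose main cells are GABAergic projection neurons, and the tissue was enriched in its shell. Expression was measured with Affymetrix Mouse Gene 1.0 ST arrays and is given as log2 values after robust multi-array analysis (RMA). Array medians over all probe sets ran from 7.02 to 7.06 in WT and from 7.08 to 7.11 in Rarb-null arrays. Interquartile ranges ran from 3.488 to 3.555 in WT and from 3.378 to 3.486 in Rarb-null arrays. Neither range overlapped between genotypes, so the deposited values kept a small difference in overall scale. Pairwise correlations across probe sets ran from 0.989 to 0.997, with no array repeated. Differences are the mean of the Rarb-null arrays minus the mean of the WT arrays, with the standard error (SE) of the limma fit, and levels are means ± SD with n = 6 for WT and n = 5 for Rarb-null. The number of arrays limits the precision of every value. The single comparison of the design asks which transcripts of the accumbens depend on the receptor, and the series title links them with Huntington disease and other neurodegenerative disorders.

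Rarb itself, read by probe set 10417713, averaged 11.75 ± 0.04 in the 6 WT arrays (11.70 to 11.81) and 9.89 ± 0.11 in the 5 Rarb-null arrays (9.72 to 10.01). The difference was -1.86 (SE 0.047), a 3.63-fold reduction, with a limma Benjamini-Hochberg adjusted p of 4.44e-11, the smallest of all genes tested. In a two-sided exact permutation test p was 0.00216, the smallest value that 462 splits of the arrays can give. Every array labelled null thus lay below every array labelled WT. The remaining signal in the null arrays was still at the 83.9th percentile of all genes, against the 97.9th in WT. The part of the gene removed by the mutation and the part read by the probe set were not given in the sources used here, so the residual level is not a measure of intact transcript.

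**Figure D1:**
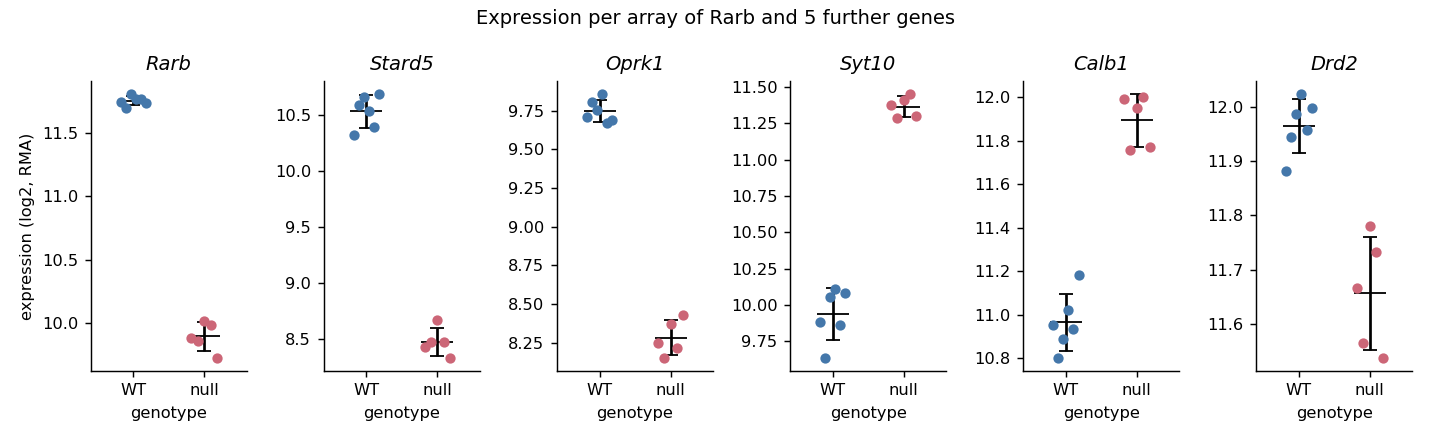
Expression (log2, RMA) of Rarb and 5 further genes in each of the 6 WT arrays (blue) and 5 Rarb-null arrays (red); horizontal bars are group means and whiskers are 1 SD, and each panel has its own axis, which does not start at 0. In all 6 panels the arrays of the 2 genotypes do not overlap.

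Stard5, which encodes a lipid-binding protein, had the largest fall in Rarb-null arrays (-2.06, SE 0.072, or 4.16-fold; 10.53 ± 0.15 in WT against 8.47 ± 0.12 in Rarb-null arrays). With Rarb set aside, it was followed by the chemokine gene Cxcl13 (-1.84, SE 0.214), the thyrotropin-releasing hormone receptor gene Trhr (-1.69, SE 0.104), the protease inhibitor gene Spint1 (-1.59, SE 0.085) and Mme (-1.53, SE 0.072), which encodes the peptide-degrading enzyme neprilysin. Oprk1, the kappa opioid receptor gene, fell by 1.46 (SE 0.052), and Kcnip1, which encodes an auxiliary subunit of voltage-gated potassium channels, fell by 1.44 (SE 0.064). Cartpt, the precursor of the CART peptide, fell by 1.27 (SE 0.069), and 1 null array (8.41) lay below the other null arrays. The remaining members of the 12 largest falls were Slf1 (-1.46), Cfap20dc (-1.29), Upb1 (-1.24), a gene of pyrimidine breakdown, and the adhesion molecule gene Clmp (-1.20). Slf1 read 7.43 in WT replicate 6 and 8.44 to 8.66 in the other WT arrays.

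The calcitonin receptor gene Calcr and the synaptotagmin gene Syt10 had the largest rises, both of 1.43 (SE 0.220 and 0.075). Calcr averaged 7.68 ± 0.53 in WT and 9.11 ± 0.27 in Rarb-null arrays, and Syt10 9.94 ± 0.18 and 11.37 ± 0.07. The transcription factor gene Ebf1 rose by 1.16 (SE 0.126), although WT replicate 6, at 8.46, lay above the other WT arrays (7.85 to 8.03). Trpc5 (1.01, SE 0.070) and Trpc6 (0.99, SE 0.068), both genes of TRPC cation channels, rose about equally, and Calb1, the gene of the calcium buffer calbindin, rose by 0.93 (SE 0.067). Kctd4 (0.98), Myo3b (0.96), Atp6v1c2 (0.87), AW551984 (0.86), Ccn3 (0.85) and Fhit (0.85) completed the 12 largest rises. For 23 of these 24 genes the limma Benjamini-Hochberg adjusted p was at most 0.00156. Ccn3 was the exception, with an adjusted p of 0.0351 that did not hold with the cortical (0.06, adjusted p = 0.849) or oligodendrocyte marker level (adjusted p = 0.0816) in the model, with a trended variance (adjusted p = 0.0722) or when any of 7 arrays was left out (WT replicates 1, 3 and 4 and Rarb-null replicates 1, 2, 3 and 5; 0.70 to 0.90, adjusted p 0.0538 to 0.0802).

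Of 11963 genes tested, 2341 passed a limma Benjamini-Hochberg adjusted p of 0.05, 905 higher and 1436 lower in Rarb-null arrays, and 4220 had an unadjusted p under 0.05. Most of these differences were small. The median fold of the called genes was 1.15, while 49 rose and 81 fell at least 1.5-fold, and 4 rose and 15 fell at least 2-fold. The arrays of the 2 genotypes did not overlap for 1334 genes (11.2%), where chance gives 0.433%. With each array centred on the median of its tested genes, the split became 1677 higher and 939 lower. This moved the share of higher calls from 38.7% to 64.1%. The split also moved with the filter on dim genes, to 1278 higher and 1229 lower without one and to 510 higher and 1209 lower with the stricter one. The count dropped to 1548 without Rarb-null replicate 3, to 1144 with the cortical marker level as a covariate and to 1054 with the oligodendrocyte marker level as a covariate.

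Genes that define striatal projection neurons were lower in Rarb-null arrays. Of 28 measured genes of projection neuron identity, 15 fell and 2 rose (19 and 2 adjusted over the list alone), and 11 did not pass the test. Rxrg, which encodes the retinoid X receptor that partners retinoic acid receptors, fell by 0.90 (SE 0.050), the sodium channel subunit gene Scn4b by 0.95 (SE 0.060), Lrrc10b by 0.60 (SE 0.041) and Rgs9, a regulator of G protein signalling, by 0.42 (SE 0.039). Id4 (0.37) and the cannabinoid receptor gene Cnr1 (0.31) were the 2 that rose, with 1 rise left without WT replicate 1, 3, 4 or 6 or Rarb-null replicate 2, 3 or 5. The median difference of the list was -0.12, and its mean level was 11.28 ± 0.04 in WT and 11.08 ± 0.05 in Rarb-null arrays (exact permutation p = 0.00216, Benjamini-Hochberg adjusted over 24 lists 0.00866). Against other genes, limma's camera gave a Benjamini-Hochberg adjusted p of 2.53e-06 with its preset correlation of 0.01 and an adjusted p = 0.393 with an estimated correlation. Cortical neuron markers stood higher in the same arrays, at 9.03 ± 0.25 in Rarb-null and 8.55 ± 0.31 in WT (exact permutation p = 0.026, adjusted 0.0519).

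Markers of both projection neuron classes took part. Among 7 measured markers of neurons with the dopamine receptor Drd2, 5 fell (6 adjusted over the list alone), led by the guanylyl cyclase gene Gucy1a1 (-0.51, SE 0.033), the orphan receptor gene Gpr52 (-0.44, SE 0.053) and Drd2 itself (-0.31, SE 0.046). Their median was -0.29 (camera, Benjamini-Hochberg adjusted p = 0.0003; adjusted p = 0.124 with an estimated correlation). Of 9 measured markers of neurons with the receptor Drd1, 4 fell and 1 rose (6 and 1 adjusted over the list alone), with Slc35d3 at -0.60 (SE 0.052), the substance P precursor gene Tac1 at -0.39 (SE 0.037), the muscarinic receptor gene Chrm4 at -0.32 (SE 0.036) and Ebf1 as the rise. The median was -0.17 (camera, Benjamini-Hochberg adjusted p = 0.0154; adjusted p = 0.2 with an estimated correlation), and the call was lost with the cortical marker level as a covariate (median -0.21, adjusted p = 0.127). Drd1 (-0.09, SE 0.034, limma Benjamini-Hochberg adjusted p = 0.0744) and the enkephalin precursor gene Penk (-0.07, SE 0.027, adjusted p = 0.103) did not pass. Both list means differed between genotypes with an exact permutation p of 0.00216.

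**Figure D2:**
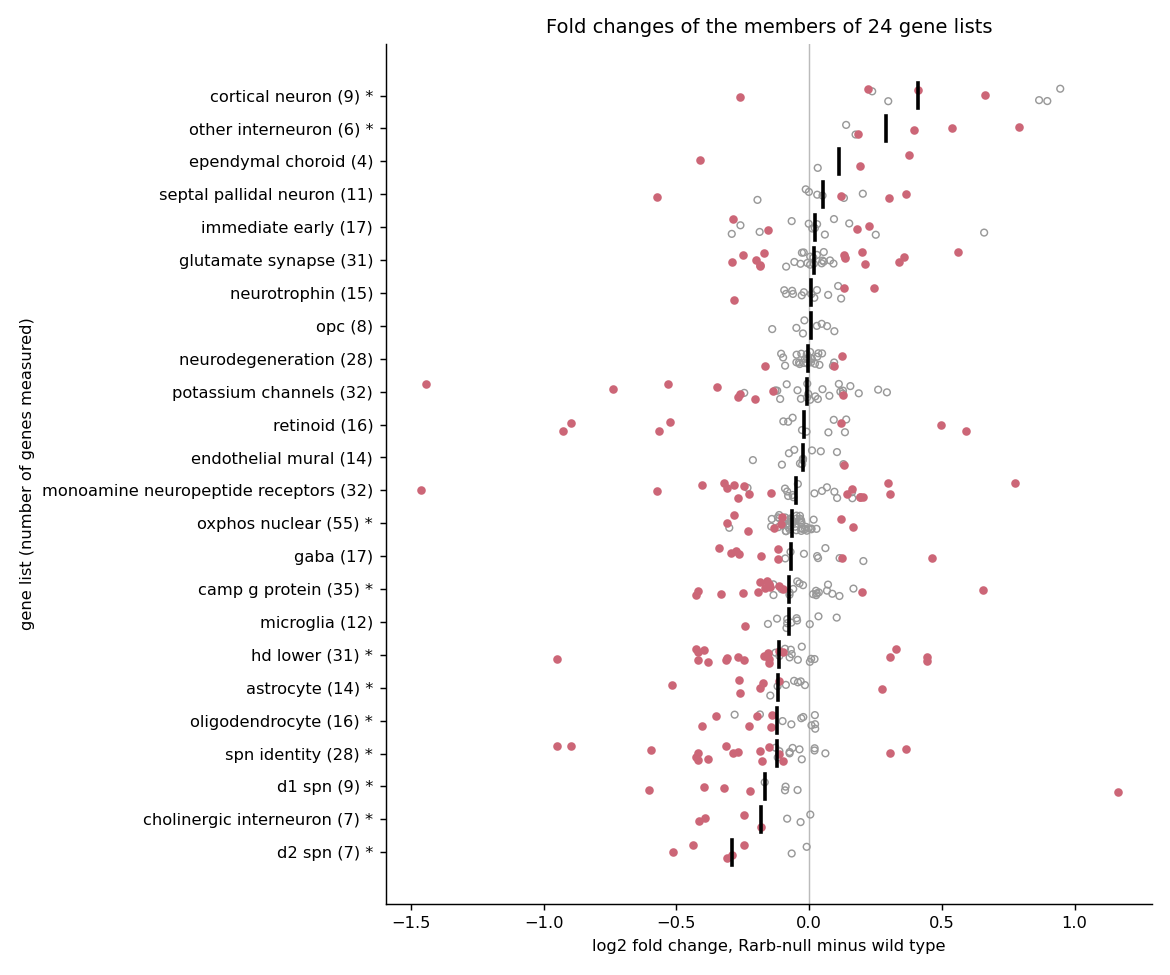
Difference in log2 expression (Rarb-null minus WT) of each measured member of 24 gene lists, with the number measured in brackets. Red points passed an adjusted p of 0.05 over all genes, open points did not, vertical bars are list medians, and an asterisk marks the 11 lists called by camera with its preset correlation, 2 higher and 9 lower; 0 of these calls held with an estimated correlation.

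Genes of retinoid transport, metabolism and reception changed in both directions. Of 16 measured members 3 rose and 4 fell (5 and 4 adjusted over the list alone). With arrays centred 6 rose and 4 fell, with a median of 0.022. Besides Rxrg, Stra6, which encodes the cell-surface transporter of retinol, fell by 0.93 (SE 0.082), and Rdh10, the gene of a retinol dehydrogenase that makes retinaldehyde, fell by 0.56 (SE 0.058). Rbp4, the gene of the retinol-carrying protein, rose by 0.50 (SE 0.057), as did the retinoic acid-binding protein gene Crabp1 by 0.59 (SE 0.069). Camera did not separate the list from other genes (median -0.018, Benjamini-Hochberg adjusted p = 0.754), while its mean level was lower in Rarb-null arrays (8.87 ± 0.05 against 8.96 ± 0.02; exact permutation p = 0.00433, adjusted 0.013). The remaining retinoic acid receptor genes gave -0.03 for Rara and -0.08 for Rarg, neither past the threshold.

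Genes known to be lower in the striatum in Huntington disease were lower here as a list. Of 31 measured, 16 fell and 4 rose (22 and 4 adjusted over the list alone). Of the 31, 16 are also in the projection neuron list, 2 in the Drd1 list and 3 in the Drd2 list. Among called genes outside those lists, Homer1 (-0.17), Egr1 (-0.15) and Rgs4 (-0.15) fell, while Slc4a11, Nrgn and Wfs1 rose. These showed no common direction. With the cortical covariate 8 of the 31 fell, as without the 3 arrays of extreme cortical marker level. In either case the falls of the projection neuron list went from 15 to 9. Scn4b, Tac1, Rgs9 and the phosphodiesterase gene Pde10a (-0.42, SE 0.043) had the smallest p. Wfs1 (0.33), the calmodulin-binding protein gene Nrgn (0.44), Slc4a11 (0.44) and Cnr1 went the other way. The median was -0.11 (camera, Benjamini-Hochberg adjusted p = 0.000163; adjusted p = 0.396 with an estimated correlation; exact permutation p of the mean 0.00216), in arrays with the higher cortical marker level given above. By contrast, of 28 genes mutated in or associated with neurodegenerative disorders, 1 fell and 2 rose (1 and 0 adjusted over the list alone): Atxn7 (-0.16), which lies 11 genes from Rarb, Tbp (0.12) and Atn1 (0.09). The huntingtin gene Htt gave 0.01, and the list did not differ from other genes (median -0.005, camera Benjamini-Hochberg adjusted p = 0.575, direction upward). The call of Atn1 was lost whichever of the 11 arrays was left out (adjusted p 0.0502 to 0.108), and that of Tbp without any array except WT replicate 1 and Rarb-null replicates 2 and 5 (adjusted p 0.0557 to 0.103).

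Nuclear genes of the respiratory chain were slightly lower, by an amount that depended on the scale of the arrays. Of 55 measured, 6 fell and 2 rose (the same counts adjusted over the list alone), with the complex I genes Ndufs1 (-0.23, SE 0.040), Ndufa1 (-0.31, SE 0.066) and Ndufa2 (-0.28, SE 0.072) leading the falls and Cox6a1 (0.17) among the rises. The median was -0.064 (camera, Benjamini-Hochberg adjusted p = 0.00645; adjusted p = 0.61 with an estimated correlation; exact permutation p of the mean 0.0195, adjusted 0.0425). With each array centred on the median of its tested genes it was -0.024, with 3 falls and 2 rises (camera, Benjamini-Hochberg adjusted p = 0.0216). The falls numbered 3 without WT replicate 5 or Rarb-null replicate 2 or 3, with 1 rise each, and 10 without WT replicate 6.

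In cyclic AMP and G protein signalling, 14 of 35 genes fell and 2 rose (15 and 4 adjusted over the list alone; 7 of the 35 are also projection neuron genes), with Rgs9, Pde10a and Pde4b (-0.33, SE 0.034) among the falls and Pde1a (0.65, SE 0.034) among the rises; Pde1a read 10.25 in WT replicate 5 and 10.37 to 10.40 in the other WT arrays. This list had a median of -0.074 and a camera Benjamini-Hochberg adjusted p of 0.0444 (adjusted p = 0.396 with an estimated correlation). The call was lost without WT replicate 4 or 6 or Rarb-null replicate 1, 4 or 5 (medians -0.096 to -0.056, adjusted p 0.0624 to 0.083) and with arrays centred (-0.034, adjusted p = 0.0623). It was also lost with the stricter filter (-0.087, adjusted p = 0.151), the cortical covariate (-0.070, adjusted p = 0.196) or the 3 arrays with extreme cortical marker levels left out (-0.055, adjusted p = 0.0989). Centring left 8 falls and 4 rises. Receptors for monoamines and neuropeptides split into 10 falls and 8 rises among 32 genes (12 and 8 adjusted over the list alone; 5 rises without WT replicate 6 or Rarb-null replicate 3 or 5), including Drd3 (-0.57, SE 0.051), Oprk1 and the muscarinic receptor gene Chrm5 (0.77, SE 0.108). Potassium channel genes gave 8 falls and 1 rise among 32 (9 and 2 adjusted over the list alone), led by Kcnip1 and Kcnk2 (-0.74, SE 0.045). The rises numbered 3 without WT replicate 2, 2 without Rarb-null replicate 2 and 4 with arrays centred, beside 7 falls. Of 17 GABA genes 7 fell and 2 rose (7 and 3 adjusted over the list alone; 1 rise when any array but WT replicates 1 and 6 and Rarb-null replicate 2 was left out), among them the synthesis gene Gad2 (-0.28, SE 0.031) and the receptor subunit genes Gabra5 (0.46, SE 0.055) and Gabrg3 (-0.34, SE 0.041). Of 31 glutamate synapse genes 6 fell and 7 rose (the same counts adjusted over the list alone), such as Grm3 (-0.18) and Grm8 (0.56). The rises of this list numbered 4 without Rarb-null replicate 1 or 5. With the cortical covariate 0 of its genes rose and 3 fell, and without the 3 arrays of extreme cortical marker level 2 rose and 4 fell.

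Growth factor genes gave 1 fall and 2 rises among 15 (the same counts adjusted over the list alone), with Sort1 at -0.28 (SE 0.034). The rises numbered 1 without WT replicate 1, 2 or 5 or Rarb-null replicate 4 or 5, and 0 without Rarb-null replicate 2 or 3. Centring of arrays gave 4 rises and 1 fall in this list. Activity-dependent immediate early genes gave 2 falls and 2 rises among 17 (3 and 3 adjusted over the list alone), with Egr3 at 0.22 (SE 0.050). The falls numbered 1 without WT replicate 2 or 6 or Rarb-null replicate 1, and 0 without WT replicate 4 or 5 or Rarb-null replicate 2, 3 or 4. There was 1 rise without Rarb-null replicate 5. With arrays centred there were 4 rises and 0 falls. With the oligodendrocyte covariate limma called 0 genes of this list. The lists of receptors, potassium channels, GABA, glutamate, growth factor and immediate early genes had camera Benjamini-Hochberg adjusted p values from 0.263 to 0.603. Among these 6 lists the exact permutation test of the mean passed after adjustment for potassium channels (p = 0.00866, adjusted 0.0208). With no filter on dim genes camera did call the lists of GABA genes, receptors and potassium channels (Benjamini-Hochberg adjusted p = 0.0161, 0.0459 and 0.0161).

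Markers of other cell types did not move as 1 group. Interneuron markers other than cholinergic ones were higher, with 4 rises among 6 genes (6 adjusted over the list alone), a median of 0.29 (camera, Benjamini-Hochberg adjusted p = 0.00171; adjusted p = 0.2 with an estimated correlation) and Npy (0.40, SE 0.071) as the smallest p. Of these rises 2 were left without WT replicate 1, 3, 4 or 6 or Rarb-null replicate 4, and 1 without Rarb-null replicate 1, 2, 3 or 5. The call of the list was lost with the cortical marker level as a covariate (median 0.06, adjusted p = 0.127). Cholinergic interneuron markers were lower, with 4 falls among 7 genes (4 adjusted over the list alone), a median of -0.18 (camera, Benjamini-Hochberg adjusted p = 0.0166; adjusted p = 0.396 with an estimated correlation) and the choline transporter gene Slc5a7 at -0.42 (SE 0.055). With the oligodendrocyte or cortical covariate the list was not called (adjusted p 0.0557 and 0.127), while its median was -0.13 and -0.17. Of the 4 falls, Chat (-0.18) and Slc18a3 (-0.25) lie 133 and 134 genes from Rarb on its chromosome. Cortical neuron markers gave 3 rises and 1 fall among 9 genes (7 and 1 adjusted over the list alone), a median of 0.41 (camera, Benjamini-Hochberg adjusted p = 0.00171; adjusted p = 0.396 with an estimated correlation) and a broad spread within genotypes, with 6 rises without WT replicate 2 and 5 without WT replicate 5. One of the 3 rises, Fezf2 (0.41), lies 18 genes from Rarb. Lamp5 rose by 0.66 (SE 0.061), whereas the glutamate transporter gene Slc17a7 ranged from 9.17 to 11.20 in WT and from 10.65 to 11.69 in Rarb-null arrays, a difference of 0.90 that did not pass (limma Benjamini-Hochberg adjusted p = 0.0639).

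Astrocyte markers were lower, with 6 falls and 1 rise among 14 genes (9 and 1 adjusted over the list alone), a median of -0.12 (camera, Benjamini-Hochberg adjusted p = 0.00286; adjusted p = 0.2 with an estimated correlation; exact permutation p of the mean 0.00216) and Slc4a4 (-0.51, SE 0.042) as the largest change. The rise was lost when any array but WT replicates 2 and 5 and Rarb-null replicate 1 was left out. Oligodendrocyte markers gave 6 falls among 16 genes (7 adjusted over the list alone), a median of -0.12 (camera, Benjamini-Hochberg adjusted p = 0.0302; adjusted p = 0.61 with an estimated correlation), with Opalin at -0.35 (SE 0.046) and the myelin basic protein gene Mbp at 0.01. That call was lost without WT replicate 1 or 6 or Rarb-null replicate 1 or 4 (medians -0.11 to -0.09, adjusted p 0.0548 to 0.205), and with the stricter filter (-0.12, adjusted p = 0.242) or cyclic loess normalisation (-0.10, adjusted p = 0.0629), the latter chosen after seeing the data. It was also short of the threshold with fry (adjusted p = 0.0585) and in the exact permutation test of the mean (p = 0.0368, adjusted 0.0668). In this list 3 falls were left without WT replicate 1, 4, 5 or 6 or Rarb-null replicate 1 or 4. Repeated quantile normalisation also left 3, and centring of arrays left 2. Septal and pallidal neuron markers gave 3 rises and 1 fall among 11 genes (4 and 1 adjusted over the list alone). These rises numbered 1 without WT replicate 4 or 6 or Rarb-null replicate 3 or 4, and 0 without Rarb-null replicate 2 or 5. Crhr2, one of the 3, fell below the expression filter when any Rarb-null array was left out, so its rise was not tested there. Microglial markers gave 1 fall among 12 (1 adjusted over the list alone), endothelial and mural markers 1 rise among 14 (0 adjusted over the list alone; 3 at an unadjusted limma p under 0.05) and ependymal and choroid plexus markers 2 rises and 1 fall among 4 (2 and 1 adjusted over the list alone; 1 rise without Rarb-null replicate 2). Oligodendrocyte precursor markers gave 0 calls among 8 genes by limma, with 2 at an unadjusted p under 0.05. These 5 lists had camera Benjamini-Hochberg adjusted p values from 0.189 to 0.737, and for the endothelial list camera pointed upward while the median was -0.023. The microglial list was called with no filter on dim genes (adjusted p = 0.0319) and the septal and pallidal list with the oligodendrocyte covariate (adjusted p = 0.0257). Of the blood list only Alas2 was measured (0.05), and of the mitochondrially encoded list 0 genes were, so neither list was tested.

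In all, camera called 11 of 24 lists, 2 higher and 9 lower, with its preset correlation. The 9 lower lists are not separate results. The Huntington disease list shares 16 measured genes with the projection neuron list and 6 with the cyclic AMP list. Centring each array brought the medians of the projection neuron, Huntington disease and astrocyte lists closer to 0 (-0.08, -0.07 and -0.08), with camera Benjamini-Hochberg adjusted p values of 2.52e-06, 9.86e-05 and 0.00504. The projection neuron median was -0.19 with the oligodendrocyte covariate and -0.08 without the 3 arrays of extreme cortical marker level, both past the threshold. With an estimated correlation it called 0, with 4 lists at an unadjusted p under 0.05, while limma's fry, which tests a list without comparing it with other genes, called 14. The medians of 9 lists, all uncalled, changed sign under other settings: retinoid, receptor, potassium channel, neurodegeneration, growth factor, immediate early, septal and pallidal, oligodendrocyte precursor and endothelial genes. Of 143 called list members, 57 lost their limma call with the oligodendrocyte covariate and 70 with the cortical covariate. Among the members named above these were Cnr1, Id4, Slc4a11, Homer1, Egr1, Atxn7, Tbp, Atn1, Ndufa1, Egr3, Chat, Slc18a3 and Fezf2 with the former. With the latter they were Cnr1, Homer1, Egr1, Rgs4, Atxn7, Tbp, Atn1, Cox6a1, Grm8, Npy, Chat, Slc18a3 and Fezf2. Both counts include members of the covariate's own list, such as Mag, Aspa and Gpr37 with the oligodendrocyte covariate and Emx1 and Fezf2 with the cortical one. The level of these genes enters the covariate, so their loss is partly built in.

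**Figure D3:**
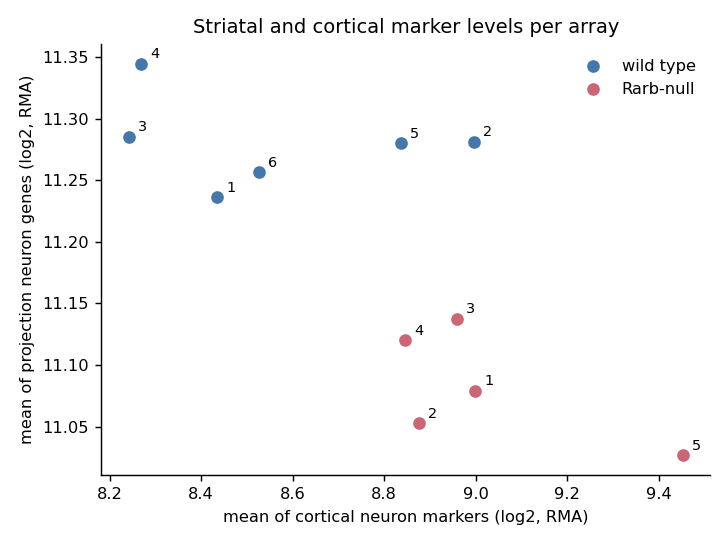
Mean log2 level of 9 cortical neuron markers (x axis) and of 28 projection neuron genes (y axis) in each array, WT in blue and Rarb-null in red, with replicate numbers beside the points; neither axis starts at 0. Projection neuron means lay between 11.24 and 11.34 in WT and between 11.03 and 11.14 in Rarb-null arrays, while the cortical means of the genotypes overlapped.

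The mutant allele was carried on a mixed C57BL/6J and 129 background, so genes beside Rarb were compared with the rest. Among tested genes within 100 protein-coding genes on either side of Rarb, 28 of 79 were called (7 higher and 21 lower), against 2312 of 11883 elsewhere (odds ratio 2.27, 95% interval 1.38 to 3.68, two-sided Fisher's exact test p = 0.00089). Cfap20dc and Fhit, among the largest changes of the whole array, lay 22 and 21 genes from Rarb, with values of -1.29 (SE 0.048) and 0.85 (SE 0.051). Thrb, the thyroid hormone receptor gene next to Rarb, fell by 0.48 (SE 0.055; limma, Benjamini-Hochberg adjusted p = 5.87e-05). Gng2, 14 genes away, rose by 0.74, and Synpr, 16 genes away, by 0.47. The share of called genes was 48.3% (14 of 29) within 25 genes of Rarb, 29.2% (7 of 24) at 26 to 50, 26.9% (7 of 26) at 51 to 100, 30.6% (15 of 49) beyond 100 and up to 200, and 18.9% (51 of 270) on the rest of the chromosome. The odds ratio was 1.28 when the whole chromosome was compared with all others (Fisher's exact test p = 0.0398) and 3.56 when genes were called with the oligodendrocyte covariate.

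**Figure D4:**
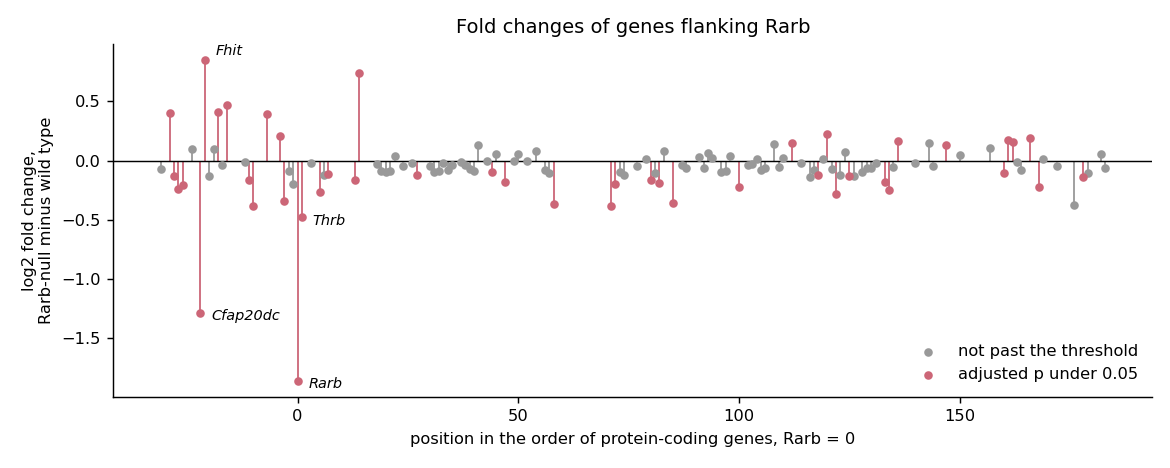
Difference in log2 expression (Rarb-null minus WT) of the tested genes within 200 protein-coding genes of Rarb, by their order on the chromosome (x axis, Rarb at 0, in genes); red points passed a limma Benjamini-Hochberg adjusted p of 0.05 and grey points did not. Apart from Rarb, the largest changes within 25 genes were those of Cfap20dc, Fhit and Gng2.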

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

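The test of glial markers against a smaller share of projection neurons was chosen only after the results were seen.

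The fall of projection neuron genes, with a list median of -0.12, was set against 3 technical explanations. Cortical tissue in the punches would dilute striatal transcripts, and cortical markers were higher in the null arrays. With their level as a covariate the median stayed at -0.0913 (Freedman-Lane permutation p = 0.0011 for the list mean). The fall was thus not accounted for by that level. The level is a mean of 9 markers, of which Lamp5 (0.77) and Rspo1 (-0.35) stayed called by limma with it in the model. It therefore measures cortical tissue imperfectly, and the covariate cannot exclude that tissue as the whole cause. Cortical tissue may also add to the size of the fall. A smaller share of projection neurons made up by glia would raise glial markers alike, yet the astrocyte median was -0.116. This cannot address a share made up by other neurons: the medians of non-cholinergic interneuron and cortical markers were 0.29 and 0.41. Compression of bright signals would move other bright genes as well, yet 0% of 10000 random lists of matched level had a median as low. A direct or indirect effect of the missing receptor in projection neurons remains a hypothesis. It was found and examined on the same 11 arrays, and no binding data were used here.

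The excess of called genes beside Rarb (odds ratio 2.27, Fisher's exact test p = 0.00089) was predicted for alleles of the 129 strain that stay linked to a targeted locus. The rise to 48.3% of called genes within 25 genes of Rarb is consistent with such passenger alleles, which may act on expression or on the binding of array probes. A local effect of the modified allele on its neighbours was not tested and stays open. The values of the 14 called genes within 25 genes of Rarb, among them Cfap20dc, Fhit, Gng2, Thrb, Fezf2 and Atxn7, therefore remain open between linkage and loss of the receptor. The same holds for Chat and Slc18a3, which lie beyond 100 and up to 200 genes away, where 30.6% were called.

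The number of called genes was set against other splits of the 11 arrays. Of 100 splits, the real one included, 1 gave as many genes as the real split (2341), and the highest other count was 1204; it came from a split that put 5 WT arrays against the 5 null arrays and the remaining WT array, and the next highest was 2. For the gene count, 1 of 100 is under the 5 of 100 set beforehand for chance. It is also the smallest share that these 100 of 462 splits can give. For lists called by camera, 3 of 100 splits reached the real 11, fewer than the 5 of 100 set beforehand for chance. The highest other count was 13, and the other splits with 11 and 13 lists kept 4 of the 5 null arrays together. The median over the other splits was 2 lists, but 1 split that kept 3 null arrays together called 10 lists and 0 genes. High list counts thus also arose without called genes, so the real count is weak evidence by itself.

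Single arrays lay far from the rest of their genotype in 17 of 270 groups examined, where chance gives about 1 in 20. In WT replicate 6, Ebf1 read 8.46, Slf1 7.43, Slc18a3 8.53, Fgfr3 9.29 and Cspg4 7.85. In WT replicate 1, Slc2a1 read 10.84, Kcnj8 6.88 and Rarres2 7.04, and in WT replicate 5 Pde1a read 10.25. In Rarb-null replicate 3, Cartpt read 8.41. In Rarb-null replicate 5, Dlgap1 read 10.95 and Kcnh1 10.79, the mean of the receptor list was 9.07, that of non-cholinergic interneuron markers 10.56 and that of cortical markers 9.45, above the cortical means of the other null arrays. The mean of glutamate synapse genes was 10.31 in WT replicate 3, and that of growth factor genes 9.45 in WT replicate 4.

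Probe sets outside the comparison also differed between genotypes by limma with Benjamini-Hochberg adjustment. Of 855 with several symbols, 32 passed (27 higher and 5 lower), and of 4179 outside the annotation table, 160 passed (96 higher and 64 lower). The largest changes among the latter were probe sets 10563959 (1.62) and 10417226 (1.19) upward and 10475800 (-0.74) and 10357878 (-0.74) downward, which have no name here.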

How the results depend on the processing

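Cyclic loess normalisation and the set without WT replicates 3 and 4 and Rarb-null replicate 5 were chosen after the data were seen. The fall of Rarb held under every setting, from -1.89 to -1.82 when single arrays were left out. The odds ratio near Rarb was 2.71, 2.27 and 2.10 within 50, 100 and 200 genes and 1.28 (95% interval 1.00 to 1.63, Fisher's exact test p = 0.0398) for the whole chromosome. Within 100 genes it was 2.20 to 3.13 without single arrays. The count of called genes went from 2341 to 1054 with the oligodendrocyte covariate, 1144 with the cortical covariate, 1341 without those 3 arrays, and 705 at an unadjusted p under 0.01 with a 1.2-fold minimum, and ranged from 1548 (without Rarb-null replicate 3) to 2580 when single arrays were left out. No called gene changed sign under the filters, scalings, variance models, array weights or omissions of arrays; 2 did with the mean of probe sets and 3 with the cortical covariate, among them Cck (from 0.79 to -0.06). The cause was not tested. Lists called numbered 11 in the comparison as reported, 6 with the cortical covariate, 0 with an estimated correlation, 15 with no filter on dim genes and 9 to 11 without single arrays; over all other settings they lay between 8 and 14. The Drd1 list had a median of -0.21 with the cortical covariate (adjusted p = 0.127) and -0.14 without the 3 arrays (adjusted p = 0.062), both short of the threshold. Both fits had fewer degrees of freedom, but the Drd2 list passed in them (camera adjusted p = 0.000999 and 0.000906). Why the Drd1 list did not was not tested. With an estimated correlation the medians were as before and the calls were lost: -0.12 for projection neuron identity, -0.17 and -0.29 for the Drd1 and Drd2 lists, -0.11 for Huntington disease genes and -0.064 for the respiratory chain. The retinoid list (-0.018) passed with fry, which does not compare it with other genes, as did the GABA, receptor and potassium channel lists (adjusted p = 0.000721, 0.00838 and 0.000439), while the oligodendrocyte list did not (adjusted p = 0.0585). The replicate numbers of the genotypes were examined as a possible pairing: deviations of same-numbered arrays correlated at 0.257, 0.056, 0.255, 0.188 and 0.425. All 5 were positive, against means of -0.135 to -0.013 with other-numbered arrays, and 3 of 5 correlated best with their own number. A factor shared by arrays of 1 number is thus possible. Number 2 was weak and the labels state no pairing, so the comparison was left unpaired. The replicate block gave 2872 genes, 2173 of them shared with the fit without it, and 9 lists. No null array shares the number of WT replicate 6, so with the block that array does not enter the difference. Left out without a block, it gave 1947 genes. The cyclic AMP (-0.075, camera adjusted p = 0.0926) and oligodendrocyte lists (-0.11, adjusted p = 0.0827) were not called with the block. Both were already lost without WT replicate 6 (camera adjusted p = 0.0723 and 0.0702). The falls of the respiratory chain list numbered 6 as reported, 10 without WT replicate 6 and 13 with the block. The rises of the cortical list numbered 3, 3 and 7. Signal over background was not measured here, and simulated changes of log2 0.25 were recovered for 74.6% of genes.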

Other observations

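Members of 3 gene families were looked at together after their values were seen; Trpc4 is also a member of the septal and pallidal list. Members of the TRPC and BRINP families moved in opposite directions. Among TRPC channel genes, Trpc5 (1.01, SE 0.070), Trpc6 (0.99, SE 0.068) and Trpc4 (0.30, SE 0.085) were higher in Rarb-null arrays, Trpc7 was lower (-1.05, SE 0.088) and Trpc1 did not pass (-0.08, SE 0.031; limma, Benjamini-Hochberg adjusted p = 0.0887). Trpc4 lost its call with the cortical covariate (0.08, adjusted p = 0.544) and without WT replicate 4 or 6 or Rarb-null replicate 2 or 5 (adjusted p 0.0506 to 0.0581). Of the BRINP family, whose founding member is named for its induction by bone morphogenetic protein and retinoic acid, Brinp1 fell by 0.69 (SE 0.028) and Brinp3 rose by 0.64 (SE 0.048), while Brinp2 gave 0.07 (SE 0.050, limma Benjamini-Hochberg adjusted p = 0.358). The neurofilament genes Nefl (-0.68, SE 0.053) and Nefm (-0.98, SE 0.094), which are neighbours on the chromosome of Rarb but 568 and 569 genes away from it, were both lower, whereas Nefh (-0.19, adjusted p = 0.057) and Ina (-0.08, adjusted p = 0.165) did not pass.

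The mean of Drd2 markers minus that of Drd1 markers differed between genotypes by -0.18 (exact permutation p = 0.00216, the smallest the design can give). Without Ebf1, whose rise is the largest of the Drd1 list, the difference was -0.03 (exact permutation p = 0.448), so the contrast between the classes rested on that gene.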
